A study of Mus musculus with 5 samples.

How the data were processed

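Gene expression was measured on Affymetrix whole-transcript arrays in 5 RNA samples, one array per sample, with biotin-labelled target. The cells were OT-I T cells, which carry a transgenic receptor for an ovalbumin peptide, moved into recipient mice that were then infected with ovalbumin-expressing Listeria. They were recovered from the spleen on day 8 and sorted by flow cytometry, per the labels' protocols. The deposited table holds 1 intensity per probe set and array. Per the submitters' processing notes, the values are RMA summaries, and the authors deposited these intensities on a linear scale, between 8.79 and 19192. The version of RMA, the way background was handled and whether other arrays were normalized in the same run are not given in the sources used here. RMA gives no detection call, so no probe set could be called absent. The number of arrays limits the precision.

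The log2 of each intensity was taken first. Median intensities per array lay between 90.3 and 95.7, but the spread differed. The SD of log2 values over all probe sets was 1.70 for TE replicate 2 and 1.74 for MP replicate 1, against 1.82 to 1.88 for the other arrays, so the columns were not quantile-matched over the 24679 probe sets listed. Of these, 21354 named exactly 1 gene in the platform annotation, 1275 named several and 2050 were not named here. Symbols were looked up by Entrez ID in a RefSeq table of GRCm38.p6, which held 21277 of the one-gene probe sets, and no symbol needed a change. The test used 19751 genes, each by its brightest one-gene probe set over all 5 arrays (893 genes had more than 1). Among the called genes only Zc3h3 and Pgap1 had more than 1. Their probe sets disagreed, with log2 fold changes of 1.59 and 0.27 for Zc3h3 and of -1.52 and -0.29 for Pgap1. No called gene was therefore borne out by a second probe set. No low values were removed. Of 446 genes on the fixed lists, 402 had such a probe set. Those without, among them some of the best known memory genes, were not analysed here.

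Groups were taken from the sample titles: 2 arrays of terminal effector (TE) cells, replicates 2 and 3, and 3 arrays of memory precursor (MP) cells, replicates 1 to 3. TE minus MP was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with its default prior, no covariate). P-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and all adjusted p-values for single genes come from this test. The fit had 3 residual degrees of freedom and a prior worth 9.01. A permutation of 2 against 3 arrays allows 10 splits and no p under 0.1, so no permutation test is given. Nothing in the labels ties the samples to separate animals, so p-values measure the spread between these samples only. The 21 gene lists (cell functions and markers of other cell types) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Fry's p tests whether a list's genes move, on balance, one way.

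The gene lists, the test, the naming rule and all alternatives but those named last were fixed before the data were examined. The rule named the sort markers, the markers the sort excluded and a preset group of T cell genes whatever their values. It added the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose higher mean reached the median of all genes (6.55 on the log2 scale), leaving out provisional symbols. From each list it took the 4 members with the smallest p among those past the threshold, or, where none passed, the 2 with the largest change. The alternatives were quantile normalization, median centring, a filter on low genes, the mean of a gene's probe sets, all probe sets, a trended and robust prior, array weights, the replicate number as a block, an adjusted p under 0.01, limma's treat against a fold of 1.2, and leaving out each array. Where 1 TE array was left out, the remaining one was assumed to vary like the MP arrays. A block for the 2 classes of arrays seen in Xist was added after seeing the data, as were the values of single genes in the fit of all probe sets, planned for the counts alone.

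The fit was tested on simulated data for the same 19751 genes, with the real gene means and 200 genes changed. Each gene's spread was drawn at random from the fitted prior and was alike on all arrays. For log2 changes of 1 it called 0% of them, for 1.5 it called 91.5% and for 2 it called 99%, with 0, 9 and 10 false calls. In this simulation a 2-fold change was therefore below what the design could call, and a gene that did not pass is not shown to be unchanged. With no gene changed, 0 genes were called. The simulated data follow limma's own model, so they do not measure false calls on arrays that differ as the real ones do. Camera called a simulated list of 20 genes shifted by 0.6 and none of 20 unshifted lists. The simulated genes varied independently, so this does not test camera on lists whose genes move together. Estimated correlations within the real lists reached 0.48.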

Results

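A pair of sorted CD8 T cell fractions from C57BL/6 mice was compared on day 8 of a Listeria infection. Both came from OT-I cells, 20000 of which had been transferred before infection with 5000 colony-forming units. The terminal effector (TE) cells were sorted as high for KLRG1, an inhibitory receptor of long-differentiated T and NK cells, and low for CD127, the IL-7 receptor alpha chain. The memory precursor (MP) cells were sorted the opposite way. The comparison asks how the transcriptomes of the 2 sorted fractions differ. There were 2 TE arrays (replicates 2 and 3) and 3 MP arrays (replicates 1 to 3), and all values are log2 RMA intensities. Arrays of the same group correlated at r = 0.970 to 0.979 across probe sets (4 pairs) and arrays of different groups at 0.965 to 0.982 (6 pairs). The highest of these was between TE replicate 3 and MP replicate 3. The number of arrays limits the precision of all values below.

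The 2 sort markers followed the labels. Klrg1 averaged 11.67 ± 0.10 (SD, n = 2) in TE cells and 7.18 ± 0.71 (SD, n = 3) in MP cells, a 22.5-fold difference (log2 fold change 4.49 ± 0.33 SE, adjusted p = 5.5e-05). Il7r, which encodes CD127, averaged 8.14 ± 0.25 in TE and 12.22 ± 0.05 in MP cells, 16.9-fold higher in MP (log2 fold change -4.08 ± 0.20 SE, adjusted p = 2.8e-06). The CD8 chains Cd8a and Cd8b1 and the leukocyte gene Ptprc were bright in both groups, with log2 differences of 0.23, 0.09 and 0.05 and adjusted p of at least 0.997. Of the markers that the sort excluded, Cd4, H2-Aa, H2-Ab1 and Ly6g had group means between 5.53 and 6.82 and did not pass the test. The log2 difference of H2-Aa was 0.48, but 1.53 without TE replicate 2 and -0.56 without TE replicate 3. Klrb1c, the gene of the NK cell antigen NK1.1, was the exception: it averaged 10.24 ± 0.39 in TE and 8.84 ± 0.29 in MP cells (log2 fold change 1.40 ± 0.24 SE, adjusted p = 0.035), although cells positive for the antigen had been gated out. That call ended without TE replicate 2 (adjusted p = 0.432), TE replicate 3 (0.0625), MP replicate 1 (0.0587) or MP replicate 3 (0.192), under quantile normalization (0.0549) and median centring (0.0597), when all probe sets were tested (0.0873) and under limma's treat (0.115). Over the alternatives its adjusted p lay between 0.0136 and 0.432.

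The arrays also differed in ways that the groups did not explain. Xist, the RNA that silences an X chromosome in female cells, was bright on TE replicate 2 (11.11), MP replicate 1 (11.38) and MP replicate 2 (11.04), and dim on TE replicate 3 (5.79) and MP replicate 3 (5.24). The Y-linked genes Eif2s3y, Kdm5d and Uty showed the opposite split, with means of 4.02, 4.97 and 4.81 on the 3 Xist-high arrays and of 8.11, 7.63 and 8.45 on the 2 Xist-low arrays, whereas the labels give all mice as male. Macrophage transcripts were bright on MP replicate 1 alone. There the lysozyme gene Lyz2 read 12.24 against 5.82 to 7.19 on the other 4 arrays, and the complement gene C1qb 10.17 against 6.36 to 7.05.

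**Figure D1:**
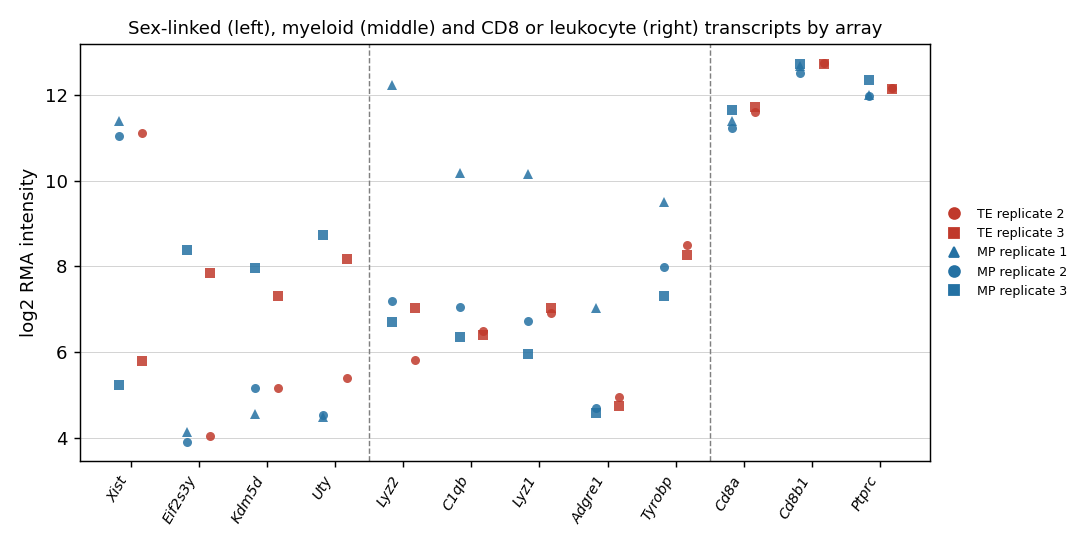
Log2 RMA intensity (y axis) of sex-linked, myeloid and CD8 or leukocyte genes (x axis) on each of the 5 arrays, 1 point per array, drawn without means because the values split within groups. Xist is above 11 on 3 arrays and below 6 on 2 with the Y-linked genes reversed, and Lyz2 reaches 12.24 on MP replicate 1 alone.

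Of 19751 genes, 30 were higher in TE and 34 were lower in TE than in MP cells, and all 64 differed by more than 2-fold. In the simulation 0% of 2-fold changes were called, so this size follows largely from the limit of the design. Besides Klrg1, the largest rises were in Gpx8, an endoplasmic reticulum peroxidase (19.3-fold, log2 fold change 4.27 ± 0.23 SE, adjusted p = 3.1e-06), and Gzma, the granule protease granzyme A (10.2-fold, 3.35 ± 0.29 SE, adjusted p = 0.00020). Then came the NK receptor genes Klra3, Klre1 and Klra8 with log2 fold changes of 2.52, 2.13 and 2.11, and Cdc20b (2.03), the secreted proteoglycan Esm1 (2.00), the transcriptional repressor Zeb2 (1.97), the fractalkine receptor Cx3cr1 (1.90), the chemerin receptor Cmklr1 (1.71) and the arsenic methyltransferase As3mt (1.63). Besides Il7r, the largest falls were in Dapl1 (9.63-fold higher in MP, log2 fold change -3.27 ± 0.21 SE, adjusted p = 2.0e-05) and in Gpr183, the oxysterol receptor that guides lymphocytes within lymphoid tissue (6.71-fold, -2.75 ± 0.32 SE, adjusted p = 0.0024). The 2 TE arrays differed in Gpr183, with log2 fold changes of -2.09 without TE replicate 2 and -3.40 without TE replicate 3. The next largest falls were in the nuclear factor Aff3 (-2.24), Myc, a driver of growth (-2.17), Ccr7, the receptor for entry into lymph nodes (-2.15), the alpha-actinin gene Actn1 (-1.84), Ssbp2 (-1.69), the interferon-induced Rtp4 (-1.68), the inhibitory receptor Btla (-1.68), the transcription factor Myb (-1.68) and the SLAM family receptor Slamf6 (-1.64). Klra3, Klra8 and their neighbours are near-identical paralogs, so which family members their probe sets read is uncertain. Gpx8, Klre1 and Klra8 averaged 5.83, 5.33 and 4.81 in MP cells. RMA values carry no measure of signal over background, so the size of these 3 differences is uncertain. The same limit applies to Klra3 and Esm1, at 6.09 and 6.14 in MP cells, and to Rtp4, at 6.27 in TE cells. All these means lie below the median of all genes (6.55). Some of these calls were lost when 1 array was left out, though a lost call need not mean a smaller difference. Without TE replicate 2 the log2 fold changes of Cmklr1, As3mt and Ssbp2 were 1.98, 1.80 and -1.79, larger than with all arrays. Those of Klra8, Btla and Actn1 were 1.56, -1.61 and -1.27, which is smaller. The difference in Actn1 was -2.41 without TE replicate 3. Without TE replicate 2 the adjusted p was 0.125 for Klra8, 0.0677 for Cmklr1, 0.0622 for As3mt, 0.0596 for Ssbp2 and 0.0622 for Btla. Without TE replicate 3 it was 0.199 for Cmklr1, 0.129 for As3mt and 0.0844 for Ssbp2. Without MP replicate 2 it was 0.0986 for Cmklr1 and 0.0702 for As3mt, and without MP replicate 3 it was 0.0893 for Klra8 and 0.143 for Cmklr1. The lowest adjusted p over the alternatives was 0.000801 for Klra8, 0.00347 for Cmklr1, 0.00507 for As3mt, 0.00491 for Ssbp2 and 0.00346 for Btla, and the highest are among the values just given.

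The groups did not overlap in any of the 64 genes, which the test itself favours. This held for 3919 of the 19751 genes tested, close to the 20% that chance alone gives. An unadjusted p under 0.05 was found for 1194 of the genes tested, where chance alone gives a share of 0.05. When all probe sets were tested, 15 of them were higher and 25 lower in TE, and of the 30 and 34 genes 12 and 19 kept the call. The counts also moved by over 1.5 times in at least 1 direction under stricter thresholds and without any array except MP replicate 1. Without single arrays they were 13 higher and 10 lower without TE replicate 2, 12 and 21 without TE replicate 3, 14 and 21 without MP replicate 2, and 12 and 18 without MP replicate 3. Without MP replicate 1, the array with macrophage transcripts, they were 27 and 40. With the Xist classes as a block they were 32 and 45. Within the Xist-high arrays they were 14 and 18, but this sets 1 TE array against 2 MP arrays, and the lone TE array was assumed to vary like the MP arrays. The Xist-low arrays, 1 of each group, give no test. Of the 34 named genes past the threshold, 17 stayed past it under each alternative that tested them: Klrg1, Il7r, Zeb2, Gzma, Ccr7, Cx3cr1, Gpx8, Klra3, Klre1, Cdc20b, Esm1, Dapl1, Gpr183, Aff3, Myc, Rtp4 and Slamf6. The call was lost for 16 of the 34 without TE replicate 2, 13 without TE replicate 3, 3 without MP replicate 1, 9 without MP replicate 2 and 11 without MP replicate 3. It was also lost for 12 when all probe sets were tested (adjusted p 0.0502 to 0.106): Klrb1c, Gzmb, Bcl2, Klra8, Cmklr1, Actn1, Bhlhe40, Itgam, Il12rb2, Cd7, Havcr2 and Cd55. Under treat it was lost for these except Klra8 and Actn1.

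**Figure D2:**
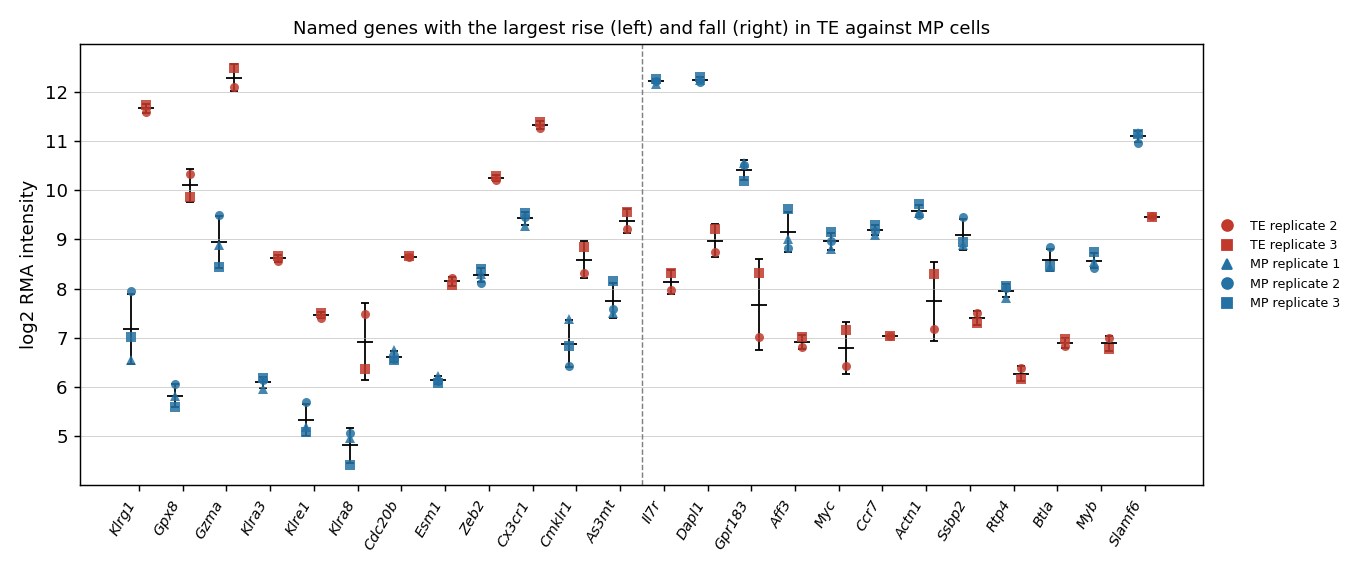
Log2 RMA intensity (y axis) of the 12 genes with the largest rise and the 12 with the largest fall in TE against MP cells (x axis), one point per array, with bars for the mean and SD of each group. The 2 TE arrays lie apart from all 3 MP arrays in each gene, with a mean difference of 4.49 log2 units for Klrg1 and of -4.08 for Il7r.

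Of 14 measured NK receptors carried by T cells (Klrg1 left out), 3 rose (Klra3, Klre1 and Klrb1c), none fell and 11 did not pass, against 6 that rose and 1 that fell when adjusted over the list alone. The median log2 fold change was 0.41 (camera adjusted p = 3.7e-08). The adjusted p was 0.16 with an estimated correlation, the highest over the 15 alternatives, of which the lowest was 2.1e-09. Without TE replicate 2 the median was 0.27. The list of NK cell markers was also called higher in TE: of 9 measured, 6 of which sit on other lists, 2 rose (Klra8 and Klrb1c), or 4 when adjusted over the list alone, and the median was 0.38 (camera adjusted p = 8.6e-05). That call was lost with an estimated correlation (adjusted p = 0.22) and under fry (0.248). Single arrays moved this median, to 0.14 without TE replicate 2, 0.70 without TE replicate 3 and 0.74 without MP replicate 1. The median deviation of these markers from the other 4 arrays was highest on TE replicate 2 (0.56) and lowest on MP replicate 3 (-0.86). Ncr1, an NK receptor gene outside the naming rule and named after its values were seen, read 7.24 on TE replicate 2 against 4.97 on TE replicate 3 and 4.54 to 5.18 on the MP arrays. Its log2 fold change of 1.27 ± 0.48 SE (adjusted p = 0.673) became 2.41 (0.00887) without TE replicate 3 and 0.14 without TE replicate 2, where it did not pass. The signalling adaptors Tyrobp and Fcer1g, which are also on the myeloid list, had log2 differences of 0.12 and 0.22, and of 0.73 and 0.77 without MP replicate 1, where both were brighter than on the other MP arrays. Fcer1g had -0.63 without TE replicate 2 and 1.06 without TE replicate 3. Neither gene passed in these fits.

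Genes of killing rose in part. Of 16 measured cytotoxic genes, Gzma and Gzmb rose, none fell and 14 did not pass. When adjusted over the list alone, 4 rose and 1 fell. Gzmb, granzyme B, averaged 11.81 ± 0.16 in TE and 10.58 ± 0.24 in MP cells (2.35-fold, adjusted p = 0.037), while Prf1, the pore former perforin, had a log2 difference of 0.65 ± 0.22 SE and did not pass (adjusted p = 0.55). The Prf1 difference was 0.42 without TE replicate 3 and 0.88 without TE replicate 2. The list median was 0.23 (camera adjusted p = 0.0011), against 0.13 without MP replicate 1 and 0.11 without TE replicate 3. It was lost with an estimated correlation (adjusted p = 0.22), under fry (0.125) and without TE replicate 3 (0.16), the lowest over the alternatives being 1.1e-05. The Gzmb call ended without TE replicate 2, TE replicate 3, MP replicate 2 or MP replicate 3, with adjusted p from 0.117 to 0.227, and under median centring (0.0597), the lowest over the alternatives being 0.00712.

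Among 12 transcription regulators tied to effector cells, Zeb2 and Bhlhe40 rose, none fell and 10 did not pass, while 3 rose if adjusted over the list alone. Zeb2 averaged 10.25 ± 0.07 in TE and 8.28 ± 0.15 in MP cells (3.93-fold, adjusted p = 0.00089). Bhlhe40 had a log2 fold change of 1.34 ± 0.24 SE (adjusted p = 0.039), and with any 1 of the 5 arrays left out its adjusted p lay between 0.0501 and 0.246. It also missed the threshold under median centring (0.0914), array weights (0.0518) and the Xist block (0.0522), the lowest over the alternatives being 0.0203. Prdm1, which encodes BLIMP1, had 1.10 ± 0.21 SE and missed the threshold (adjusted p = 0.066), but passed it under quantile normalization (0.0246) and with the Xist block (0.0495), the highest over the alternatives being 0.280. Tbx21, which encodes T-bet, had 0.44 ± 0.21 SE (95% interval -0.02 to 0.91) and Id2 had -0.20 ± 0.20 SE (-0.63 to 0.24). The list median was 0.18 (camera adjusted p = 0.00021), against 0.39 without TE replicate 2 and 0.30 without MP replicate 3. The call was lost with an estimated correlation (adjusted p = 0.22), under fry (0.125) and without TE replicate 3 (0.081), the lowest over the alternatives being 1.3e-06.

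Genes high in naive CD8 T cells had the lowest median difference of the 21 lists. Of 12 measured members, 4 fell in TE (Dapl1, Ccr7, Actn1 and the complement regulator Cd55), none rose and 8 did not pass. When adjusted over the list alone, 7 fell. Of the 12 genes, 5 sit on other lists. The median log2 fold change was -0.82 (camera adjusted p = 3.4e-14). The adjusted p was 0.16 with an estimated correlation, the highest over the alternatives, of which the lowest was 1.1e-14. Dapl1 averaged 12.24 ± 0.05 in MP and 8.98 ± 0.33 in TE cells, and Ccr7 9.18 ± 0.10 and 7.03 ± 0.00. Actn1 lost its call without TE replicate 2 (adjusted p = 0.15), MP replicate 2 (0.069) or MP replicate 3 (0.13), and Cd55 without TE replicate 2 (0.062), TE replicate 3 (0.17) or MP replicate 3 (0.12). The lowest over the alternatives was 0.00337 for Actn1 and 0.0118 for Cd55.

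Of 15 measured regulators tied to memory or naive cells, Myb alone fell in TE, and the other 14 did not pass, while 4 fell if adjusted over the list alone. Myb averaged 8.57 ± 0.16 in MP and 6.89 ± 0.16 in TE cells (3.20-fold, adjusted p = 0.0033), with an adjusted p of 0.0547 without TE replicate 3 and of 0.00283 at the lowest over the alternatives. Eomes, Lef1, Bcl6, Foxo1 and Id3 had log2 differences of -0.21 ± 0.22, 0.07 ± 0.21, -0.02 ± 0.23, -0.42 ± 0.24 and -0.41 ± 0.22 (SE). Over the alternatives they ranged, in this order, from -0.34 to -0.08, -0.06 to 0.15, -0.24 to 0.19, -0.53 to -0.22 and -0.61 to -0.20. The list median was -0.22 (camera adjusted p = 1.1e-05), but the adjusted p was 0.189 under fry and 0.33 with an estimated correlation, the highest over the alternatives, of which the lowest was 8.5e-07. That median was -0.34 without TE replicate 2, -0.33 without MP replicate 2 and -0.12 without MP replicate 3.

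Costimulatory and inhibitory receptors moved in both directions, mostly down in TE. Of 23 measured, 4 fell (Slamf6, Btla, Ctla4 and Cd7), 1 rose (Havcr2, which encodes TIM-3) and 18 did not pass. Adjusted over the list alone, 8 fell and 1 rose. Ctla4 lies outside the naming rule and was named after its values were seen (log2 fold change -1.36, adjusted p = 0.0355). Its adjusted p was 0.232 without TE replicate 3, 0.0561 without MP replicate 1, 0.174 without MP replicate 2 and 0.129 without MP replicate 3, the lowest over the alternatives being 0.0146. Slamf6 averaged 11.10 ± 0.11 in MP and 9.46 ± 0.01 in TE cells (3.11-fold, adjusted p = 0.0031). Cd7 had a log2 fold change of -1.24 ± 0.20 SE (adjusted p = 0.022) and Havcr2 of 1.23 ± 0.21 SE (adjusted p = 0.035). Both of these calls ended without TE replicate 2, TE replicate 3, MP replicate 2 or MP replicate 3, with adjusted p from 0.102 to 0.167 for Cd7 and from 0.0889 to 0.229 for Havcr2, which was also lost under median centring (0.0576). Over the alternatives the lowest were 0.00188 and 0.0196. Cd27, a costimulatory receptor, had -0.95 ± 0.21 SE and did not pass (adjusted p = 0.13), though it did with a trended and robust prior (0.0363), the highest over the alternatives being 0.846. The list median was -0.27 (camera adjusted p = 3.5e-06, and adjusted p = 0.16 with an estimated correlation, the highest over the alternatives, of which the lowest was 7.6e-07).

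Homing receptors split evenly. Of 24 measured, Cx3cr1 and Itgam, the integrin CD11b, rose in TE, Ccr7 and the chemokine receptor Cxcr3 fell, and 20 did not pass. Adjusted over the list alone, 3 rose and 4 fell. Cxcr3 averaged 11.34 ± 0.04 in MP and 9.81 ± 0.08 in TE cells (2.89-fold, adjusted p = 0.0043; 0.0622 without TE replicate 2, and 0.000487 at the lowest over the alternatives), and Cx3cr1 9.43 ± 0.14 and 11.33 ± 0.09. Itgam had 1.42 ± 0.24 SE (adjusted p = 0.029), and without TE replicate 2, TE replicate 3, MP replicate 2 or MP replicate 3 its adjusted p was 0.108 to 0.312. It was also lost under quantile normalization (0.0514), the lowest over the alternatives being 0.00725. S1pr5, the egress receptor of effector and NK cells, had 1.67 ± 0.33 SE and missed the threshold (adjusted p = 0.073), but passed it without TE replicate 2 (2.26, adjusted p = 0.0286), under quantile normalization (0.0461), without low genes (0.0489) and with the Xist block (0.0264). Without TE replicate 3 it had 1.09 and an adjusted p of 0.316, the highest over the alternatives. The list as a whole did not pass (median 0.08, camera adjusted p = 0.83).

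**Figure D3:**
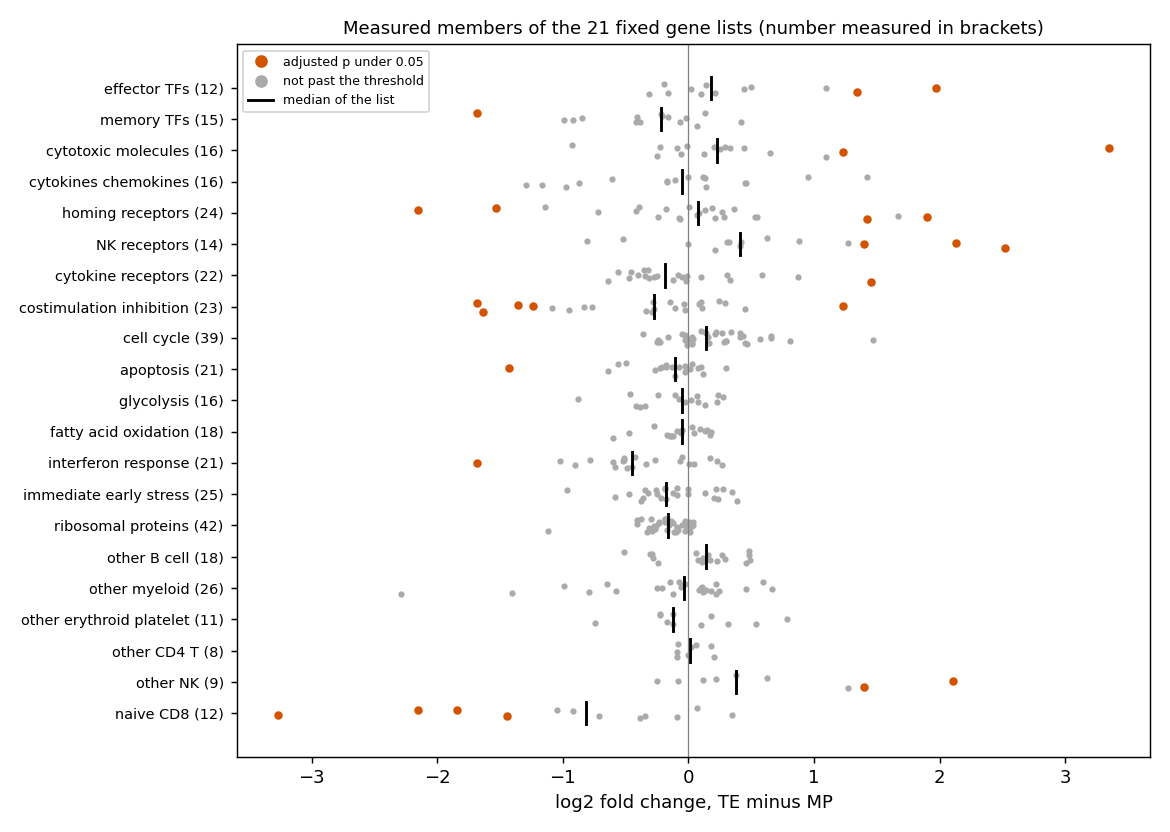
Log2 fold change, TE minus MP (x axis), of each measured member of the 21 fixed gene lists (y axis, number measured in brackets), with genes past the threshold in orange and the list median as a black bar. The naive CD8 list has a median of -0.82 and the NK receptor list a median of 0.41.

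Of 21 interferon-stimulated genes measured, Rtp4 fell in TE (7.95 ± 0.13 in MP and 6.27 ± 0.15 in TE cells, 3.21-fold, adjusted p = 0.0031), none rose and 20 did not pass, against 4 that fell when adjusted over the list alone. The median was -0.45. Camera called the list lower in TE (adjusted p = 6.2e-08), but the call was lost under fry (0.125) and with an estimated correlation (0.21, the highest over the alternatives, of which the lowest was 4.4e-10). Among 42 ribosomal protein genes none passed, 36 had a negative sign and the median was -0.16. Rpl12 had -1.12 ± 0.26 SE (adjusted p = 0.164), the 1 gene that fell when adjusted over the list alone, and Rpsa had -0.41 ± 0.24 SE (adjusted p = 0.946). These differences were -0.72 and -0.08 without TE replicate 2, and -1.51 and -0.73 without TE replicate 3. With all arrays kept, the other probe sets of Rpsa gave -0.25, -0.04, -0.41 and -0.19. Camera gave an adjusted p of 0.00021, which was lost with an estimated correlation (adjusted p = 0.66), under fry (0.557), without TE replicate 2 (0.22; median -0.08) and without MP replicate 2 (0.067; median -0.10), the lowest over the alternatives being 1.2e-06.

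Of 21 apoptosis genes, Bcl2, the survival factor, fell in TE (9.26 ± 0.35 in MP and 7.83 ± 0.18 in TE cells, 2.69-fold, adjusted p = 0.028), and 20 did not pass. No other member fell when adjusted over the list alone. The Bcl2 call ended without TE replicate 2, TE replicate 3 or MP replicate 3, with adjusted p from 0.125 to 0.188, and under quantile normalization (0.0546), the lowest over the alternatives being 0.0186. The list's median was -0.10 (camera adjusted p = 0.016, and adjusted p = 0.22 with an estimated correlation). It was also lost under fry (adjusted p = 0.248) and quantile normalization (0.14), without low genes (0.19), without TE replicate 2 (0.24) and without MP replicate 3 (0.11), the lowest over the alternatives being 0.0072. The median was -0.06 without MP replicate 2 and -0.04 without MP replicate 3. Of 39 cell cycle genes none passed, over all genes or when adjusted over the list alone. The cyclin gene Ccnb2 had 1.47 ± 0.47 SE (adjusted p = 0.49; 2.06 with adjusted p = 0.0109 without MP replicate 1), Ccna2 had 0.81 ± 0.42 SE (adjusted p = 0.92; log2 differences of 1.43 without TE replicate 2 and 0.18 without TE replicate 3) and the proliferation marker Mki67 had 0.57 ± 0.25 SE (adjusted p = 0.77). The list median was 0.14 (camera adjusted p = 0.0045). The call was lost with an estimated correlation (adjusted p = 0.49), under fry (0.551), without TE replicate 3 (0.79) and without MP replicate 3 (0.055), the lowest over the alternatives being 1.1e-06, and the median was 0.25 without TE replicate 2 and 0.03 without TE replicate 3. It was 0.02 within the Xist-high arrays and 0.41 in the Xist-low pair.

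The other functional lists did not pass. Of 22 cytokine receptors, Il12rb2, a chain of the IL-12 receptor, rose in TE (10.25 ± 0.15 against 8.80 ± 0.47 in MP cells, adjusted p = 0.041), although without any 1 of TE replicate 2, TE replicate 3, MP replicate 1 or MP replicate 2 its adjusted p was 0.0543 to 0.231. It was also lost under median centring (0.078), the lowest over the alternatives being 0.0211. Adjusted over the list alone, 2 receptors rose. Il2rb, shared by the IL-2 and IL-15 receptors, had -0.47 ± 0.23 SE (adjusted p = 0.90). Its difference was -0.22 without TE replicate 2 and -0.72 without TE replicate 3. The list's camera adjusted p was 0.32. Among 16 cytokine and chemokine genes none passed. Ccl9 had 1.43 ± 0.28 SE (adjusted p = 0.077; 0.0411 without MP replicate 2 and 0.0154 with the Xist block), Tnf had -1.30 ± 0.26 SE (adjusted p = 0.086) and Ifng had 0.45 ± 0.27 SE (adjusted p = 0.95), with a camera adjusted p of 0.32. The Ifng difference was 0.16 without MP replicate 3 and 0.67 without MP replicate 1. When adjusted over the list alone, 2 of the 16 genes rose and 4 fell. None of 16 glycolysis genes, 18 genes of fatty acid oxidation or 25 immediate early and stress genes passed, with camera adjusted p of 0.18, 0.32 and 0.12. Only 1 glycolysis gene fell when adjusted over the list alone. Their largest differences were in Pdk1 (-0.88 ± 0.20 SE) and Slc16a1 (-0.47 ± 0.31), in Decr1 (-0.60 ± 0.26) and Eci1 (-0.48 ± 0.25), and in Ier3 (-0.96 ± 0.25) and Egr1 (-0.59 ± 0.20). As single arrays were left out, Slc16a1 ranged from -0.80 to -0.18, Decr1 from -0.79 to -0.35 and Eci1 from -0.81 to -0.14. Camera did call glycolysis (0.020), fatty acid oxidation (0.044) and cytokine receptors (0.039) lower in TE without MP replicate 1, and these 3 and the stress genes without TE replicate 3 (0.0035, 0.031, 0.028 and 0.0010).

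Markers of other cells did not separate the groups, apart from those of NK cells given above. The camera adjusted p was 0.32 for 18 B cell markers, 0.82 for 26 myeloid markers, 0.73 for 11 red cell and platelet markers and 0.82 for 8 CD4 T cell markers, and no member passed, also when adjusted over the list alone. The red cell and platelet list had a median of -0.12 but a mean of 0.03, and its test pointed upwards. B cell markers were called higher in TE without MP replicate 2 (adjusted p = 0.0464) and red cell and platelet markers without TE replicate 2 (0.0236). The largest B cell differences were in Cd79b (-0.51 ± 0.23 SE) and H2-Eb1 (0.49 ± 0.25). Those of red cells and platelets were in Car1 (0.79 ± 0.29) and Pf4 (-0.74 ± 0.55), and those of CD4 T cells in Foxp3 (0.21 ± 0.21) and Cd4 (0.18 ± 0.20). Pf4 read 7.59 on MP replicate 1 against 5.14 to 5.30 on the other arrays, and its difference was 0.06 without MP replicate 1. Car1 had 0.41 without TE replicate 3 and 1.16 without TE replicate 2. The myeloid list depended on MP replicate 1. Lyz2 and C1qb had log2 differences of -2.29 ± 1.18 SE and -1.41 ± 0.78 SE, and of -0.52 and -0.25 without that array. The list was then called higher in TE (median 0.26, adjusted p = 0.0043). Without MP replicate 3 it was called lower in TE (adjusted p = 0.0068).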

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

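Klrg1 and Il7r kept their calls in all 15 alternatives that tested them, and no called list changed direction. The 64 called genes have groups that do not overlap, so leaving out an array could not turn their direction. When all probe sets were tested, 12 of the 30 genes higher in TE kept the call, and 15 probe sets were higher. The number of genes higher in TE fell from 30 to 14 under limma's treat at a fold of 1.2 and to 10 at an adjusted p under 0.01. The number lower in TE fell from 34 to 19 under treat and to 18 at the adjusted p under 0.01. Stricter thresholds give fewer calls by construction; with all probe sets the prior was worth 6.79 degrees of freedom in place of 9.01. Leaving out each array gave 12 to 27 genes higher and 10 to 40 lower in TE. Other settings kept both counts within 1.5 times. The median log2 fold change of all genes stayed between -0.04 and 0.03. With the replicate block, 27 genes were higher and 40 lower in TE, 24 and 25 of them among the original calls. MP replicate 1 has no TE partner, so the block leaves its values out of the difference. Deviations from the group means correlated across genes at r = -0.02 between the arrays numbered 2 and 0.29 between those numbered 3. They also correlated at 0.28 between TE replicate 2 and MP replicate 1. With 2 TE arrays the TE deviations mirror each other, so these correlations cannot decide on pairing. Arrays of the same number shared an Xist class. Xist read 11.11 and 11.04 on those numbered 2, and 5.79 and 5.24 on those numbered 3. MP replicate 1 was Xist-high too (11.38). The highest correlation of any 2 arrays was between those numbered 3 (r = 0.982). Nothing in the labels makes a number a shared mouse or day, so a pairing stays open. The block lost the calls of Gzmb (adjusted p = 0.050), Bcl2 (0.062), Cd55 (0.053) and Bhlhe40 (0.096) among the named genes, and gained those of Ccl9 (0.0292), Tnf (0.0436) and Ccnb2 (0.0295). It called 6 lists higher and 9 lower in TE, among them the myeloid list higher (0.00332) and cytokine receptors (0.0262), glycolysis (0.0245) and fatty acid oxidation (0.0415) lower, which were not called without it. Of the 21 gene lists, 5 were called higher and 6 lower in TE, and camera with an estimated correlation called 0 in either direction. Fry called 1 higher (NK receptors) and 2 lower (naive CD8 genes and costimulatory or inhibitory receptors). Without TE replicate 3, 2 lists were higher and 10 lower. Over the arrays left out in turn, the lists higher in TE numbered 2 to 6 and those lower 4 to 10. All 11 called lists stayed called without MP replicate 1 and with the Xist classes as a block. The block could by design alter the differences little, so it is no separate test of the lists. The median of the regulators tied to memory or naive cells was -0.12 within the Xist-high arrays and -0.52 in the Xist-low pair. That of ribosomal protein genes was -0.23 and -0.08. The median of each called list had the same sign in both classes. RMA values carry no measure of signal over background, so differences of genes dim in either group may be understated. Examples are Gpx8, Klre1 and Klra8 in MP cells, and Rtp4 and Ctla4 in TE cells. In simulation 0% of 2-fold changes were called.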

Other observations

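Of the tests below, those of myeloid RNA on MP replicate 1, of calls and fold changes kept with the Xist block and of calls and fold changes kept without MP replicate 1 were chosen after their results had been seen in part or in full, and the Xist block itself was added after seeing the data. Several genes past the threshold lie outside the fixed lists and the naming rule; those given here were chosen after their values were seen. Higher in TE were Dapk2, a death-associated kinase (log2 fold change 1.54 ± 0.20 SE, adjusted p = 0.0048), Stmn1, the microtubule regulator stathmin (1.55 ± 0.27 SE, adjusted p = 0.035), Suox, sulfite oxidase (1.24), and Zeb2os, the antisense neighbour of Zeb2 (1.59). Lower in TE were Pecam1, the adhesion molecule CD31 (-1.59 ± 0.21 SE, adjusted p = 0.0048), Tlr1 (-1.61) and the paralogs Ctla2a and Ctla2b (-1.59 and -1.37). So were the adhesion protein Emb (-1.50), Ddb2, a DNA damage sensor (-1.35), and Sgk3, a kinase related to AKT (-1.17). These values come from the same limma fit. Each of these calls ended under some alternative, which need not mean that the difference rests on 1 array. Without TE replicate 2 the log2 fold changes of Dapk2, Ctla2a and Emb were 1.56, -1.67 and -1.61. Those of Ctla2b and Ddb2 shrank to -1.03 and -1.21. With all arrays kept, Ctla2b lost its call under quantile normalization (0.0531) and median centring (0.0706). Ddb2 lost it when all probe sets were tested (0.0530) and under treat (0.0788). Over the alternatives the adjusted p reached 0.0598 for Dapk2 (without TE replicate 2), 0.330 for Stmn1, 0.145 for Suox, 0.426 for Zeb2os, 0.0818 for Pecam1, 0.0798 for Tlr1 (without TE replicate 3), 0.0844 and 0.453 for Ctla2a and Ctla2b, 0.0979 for Emb, 0.260 for Ddb2 and 0.211 for Sgk3.

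Probe sets that named several genes or none were left out of the comparison. In a fit of all probe sets 8 of these 3325 passed the threshold, 3 higher and 5 lower in TE. The 3 higher ones all read members of the Klra family at once, with log2 fold changes of 3.16, 3.05 and 2.19. Among the lower ones, a probe set naming Hmgb1 and 2 of its near copies fell by 2.39, and 1 naming Apol7e and Apol7b fell by 1.52 on the log2 scale. The other 3 are not named here.

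Xist was bright on 3 arrays and dim on 2, in both groups, while the labels give all mice as male. A candidate explanation is that the RNA of the 3 Xist-high arrays came from cells without a Y chromosome. Eif2s3y, Kdm5d and Uty were all lower on each of those arrays, by a median of 3.64 log2 units, in a test that could have come out otherwise, and whether donors or labels differ from the record stays open. Both Xist classes occurred in both groups, and the groups did not overlap in any of the 64 called genes. This split alone could therefore not have produced the TE to MP calls. The block could change them little by design, so it is no separate test. With it, 93.8% of the 64 called genes stayed past the adjusted threshold (28 of 30 higher and 32 of 34 lower in TE). The other 4, named after their values were seen, lost the call (adjusted p 0.0522 to 0.0600). They kept at least 97.7% of their log2 fold change, which the block could by design alter little. With the block, which takes 1 residual degree of freedom, it went from 1.34 ± 0.24 SE to 1.32 ± 0.24 for Bhlhe40 and from 1.17 ± 0.22 to 1.14 ± 0.21 for Lamc1. It went from -1.44 ± 0.26 to -1.44 ± 0.27 for Cd2ap and from -1.15 ± 0.21 to -1.15 ± 0.21 for Dusp10. Sex is no group of the design, so no biological explanation was tested.

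MP replicate 1 alone carried macrophage transcripts, with the largest excesses over the mean of MP replicates 2 and 3 in Prg4 (5.55), Wfdc17 (5.50), Lyz2 (5.29) and Fn1 (5.15). The 26 myeloid markers fixed beforehand, 2 of them also on the NK cell list, had a median excess of 0.67, at percentile 100 of 10000 random lists matched on expression, whereas B cell, red cell, CD4 T cell and NK cell markers lay at percentiles 6.06, 11, 66.8 and 96.5. This is consistent with RNA from macrophages or related cells, although C1qa had an excess of 0.90 against 3.46 for C1qb, S100a8 and S100a9 had -0.14 and -0.59, and the sort had excluded MHC II and Gr1. The narrower value range of the array is argued against, since after quantile normalization the median excess was 0.71, again at percentile 100. In each of the 34 genes called higher in MP, MP replicates 2 and 3 also lay above both TE arrays. Such cells on MP replicate 1 could therefore not alone have produced these calls. Of the 34, 27 stayed past the adjusted threshold without MP replicate 1, against 21 without MP replicate 2 and 18 without MP replicate 3. These counts do not decide on a source, since MP replicate 1 also had the lowest array weight (0.84, against 0.93 to 1.28 for the others). The other 7 lost the call without MP replicate 1 (adjusted p 0.0556 to 0.106). Their log2 fold changes, -1.15 to -1.44 before (SE 0.20 to 0.26), were then -1.02 to -1.36 (SE 0.22 to 0.27), at least 84.2% of the original. Each fold shrank, and the SE grew in all but Cd2ap. A fold could largely remain in any case, since MP replicates 2 and 3 also lay above both TE arrays. All 7 read higher on MP replicate 1 than the mean of MP replicates 2 and 3, by 0.03 to 0.69. A partial share of such cells in these differences therefore stays open. No biological explanation was tested, since the design gives none for a single array.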
